A study of Homo sapiens with 6 samples.

How the data were processed

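Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in CCLP1, an established human cell line, with 1 library per group and 6 libraries in all. The groups were a YAP antibody, a TEAD antibody, a tagged YAP mutant (Flag-Bio-YAP5SA, called YAP5SA here), an unrelated IgG, input DNA and BirA. The series' design text describes BirA as the control of the tagged protein. Per the labels' protocols, fixation lasted 10 min in 1% formaldehyde, glycine at 0.125 M stopped it, and sonication gave fragments of about 250 bp. The same text counts 8 samples, 3 of them YAP runs made with 2 antibodies. The YAP library analysed here is 1 of these runs; which run it is was not established, and the other runs were not analysed here. Peak lists of the YAP, TEAD and YAP5SA libraries were analysed. The IgG, input and BirA libraries were not used here, so no background measured in them stands beside the values.

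Per the submitters' processing notes, reads were aligned to hg19 with Bowtie2. Each deposited list gives a chromosome, a start, an end, a peak name that begins with MACS, and a score per peak. The score is the authors' deposited value. It runs from 50 to 3100 in each list and was read as 10 times the negative log10 of the peak caller's p-value, from its range alone. The version of the peak caller, its threshold and the control library set against each list are not given in the sources used here. The lists could have been called against one control, so part of their overlap can come from it. Scores were used only to rank peaks within their own list. The lists are deposited per library, with 1 list for each. Read depth cannot be read from peak lists and is unknown for all 3.

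Coordinates were read as half-open intervals counted from 0 and are printed counted from 1 in hg19. The start of 1 TEAD peak lay below 0 and was set to 0. The build was checked against the lists. The last peak on chromosome 1 ends at base 249238330, beyond the last gene in the GRCh38.p14 gene table, and 37 contigs have a peak. That gene table was therefore not used with the peaks, no hg19 annotation or sequence was used here, and peaks carry no gene, promoter or motif assignment. The planned results on promoters, motifs and fixed gene lists were not run for this reason.

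A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Observed shares were compared with 1000 random placements of the first list on the same chromosomes, between the first and last base covered by any list, with peak widths kept. This permutation test was one-sided, and the smallest p it can give is 0.001. The 6 ordered pairs of lists formed one family with Benjamini-Hochberg adjustment. Shares carry exact Clopper-Pearson 95% intervals, which treat peaks as independent and cover counting error only. A cluster was 3 or more peaks of a list, each within 12.5 kb of the next, a distance in common use for joining enhancers into super-enhancers. The scores of shared and unshared peaks were compared as the probability that a shared peak scores higher, with a two-sided permutation test of 100000 resamples and an interval from 1000 bootstrap draws. Fisher's exact test, two-sided, was used for odds ratios. With 1 library per group, every test compares these lists and not conditions, and no replicate error can be given.

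The regions named in the text were, for each list, the 10 peaks with the highest score and the 5 clusters with the most peaks, a rule fixed before the data were examined. Regions outside that rule are said to be so. Alternatives fixed in advance were a reciprocal overlap of 50%, peak centres within 250 bp, the higher-scoring 50% of each list, lists limited to 3867 peaks, random shifts of up to 500 kb, omission of chromosome 1, windows of 200 bp around peak centres, peaks of middling width, and cluster distances of 5 kb and 25 kb. Lists limited to 3867 peaks kept the highest-scoring ones. A further alternative was chosen after seeing the data and is called "without repeat-like regions". It leaves out contigs, peaks over 1 kb and peaks within 2 Mb of a stretch of over 2.5 Mb that has no peak in any list, of which there are 21. It kept 3278 YAP, 8548 TEAD and 9307 YAP5SA peaks. It also drops some strong peaks far from such stretches because they are wide, such as the TEAD peak on chromosome 5 from 1326297 to 1329202.

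The overlap and cluster code was tested on simulated lists of the real sizes. All 200 planted overlaps were recovered for each of the 6 ordered pairs, as were the 150 planted cluster members in the TEAD list of 9321 peaks. The 6 overlap counts equalled those of bedtools 2.31.1, both for any overlap and for a reciprocal overlap of 50%. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.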

Results

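Genome-wide binding was measured in the human cell line CCLP1 by ChIP-seq for YAP, a transcriptional co-activator of the Hippo pathway, for TEAD, the DNA-binding partner of YAP, and for YAP5SA, a tagged YAP mutant in which serines targeted by LATS kinases are replaced by alanine. The YAP list held 3867 peaks, the TEAD list 9321 and the YAP5SA list 9616. Median peak widths were 312 bp for YAP (interquartile range 259 to 370), 214 bp for TEAD (163 to 303) and 164 bp for YAP5SA (140 to 206). TEAD peaks had a median score of 76.2 (interquartile range 60.4 to 133), while the YAP median was 57.9 (53.8 to 65.9) and the YAP5SA median 56.95 (52.2 to 64.4). YAP and YAP5SA peaks thus lay mostly close to the lowest score listed, which was 50. In the YAP list 29 peaks were wider than 5 kb and made up 27.7% of the sequence it covered, against 9 peaks and 2.83% for TEAD and 8 peaks and 5.36% for YAP5SA. Each list comes from 1 library, so no value below has a replicate error.

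The first comparison asked how far the sites of YAP, TEAD and the tagged mutant coincide. TEAD and YAP5SA shared the most peaks: 512 of 9321 TEAD peaks overlapped a YAP5SA peak (5.49%, 95% interval 5.04 to 5.98), 30.8 times the mean of random placements. In the other direction 523 of 9616 YAP5SA peaks overlapped a TEAD peak (5.44%, 4.99 to 5.91), 33.2 times the placed mean. Of the YAP peaks, 320 overlapped a TEAD peak (8.28%, 7.43 to 9.19; 16.3 times) and 102 a YAP5SA peak (2.64%, 2.16 to 3.19; 7.54 times). YAP peaks were met by 418 TEAD peaks (4.48%, 4.07 to 4.92) and by 111 YAP5SA peaks (1.15%, 0.951 to 1.39). Most peaks of each list therefore had no partner in either of the others at the thresholds used by the authors.

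In all 6 ordered pairs, 0 of 1000 random placements reached the observed overlap (one-sided permutation test, p = 0.001, the smallest it can give, and the same after Benjamini-Hochberg adjustment). Against random shifts of up to 500 kb, which keep each peak in its neighbourhood, the ratios to the placed mean were lower: 6.15 for YAP in TEAD, 5.73 for YAP in YAP5SA, 19.2 for TEAD in YAP5SA, 6.42 for TEAD in YAP, 3.62 for YAP5SA in YAP and 15.5 for YAP5SA in TEAD. The setting without repeat-like regions was chosen after seeing the data. There the share of YAP peaks in TEAD was 4.48% and of TEAD peaks in YAP 1.76%. With a reciprocal overlap of 50% all 6 shares fell. They were 4.63% for YAP in TEAD, 1.60% for YAP in YAP5SA and 3.34% for TEAD in YAP5SA. The others were 1.92% for TEAD in YAP, 0.645% for YAP5SA in YAP and 3.23% for YAP5SA in TEAD. The ratios to the placed mean rose for all 6 pairs in both settings. These ratios ran from 16.1 to 41.9 without repeat-like regions and from 38.4 to 81.8 with a reciprocal overlap of 50%. With peak centres within 250 bp TEAD in YAP was 2.85%. Among the higher-scoring 50% of each list TEAD in YAP5SA was 8.41% and the reverse 8.28%. With lists of 3867 peaks TEAD in YAP5SA was 9.31%, the reverse 9.44%, TEAD in YAP 7.03% and YAP5SA in YAP 2.12%. The shares of YAP peaks fell in that setting, to 5.69% in TEAD and 1.91% in YAP5SA.

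**Figure D1:**
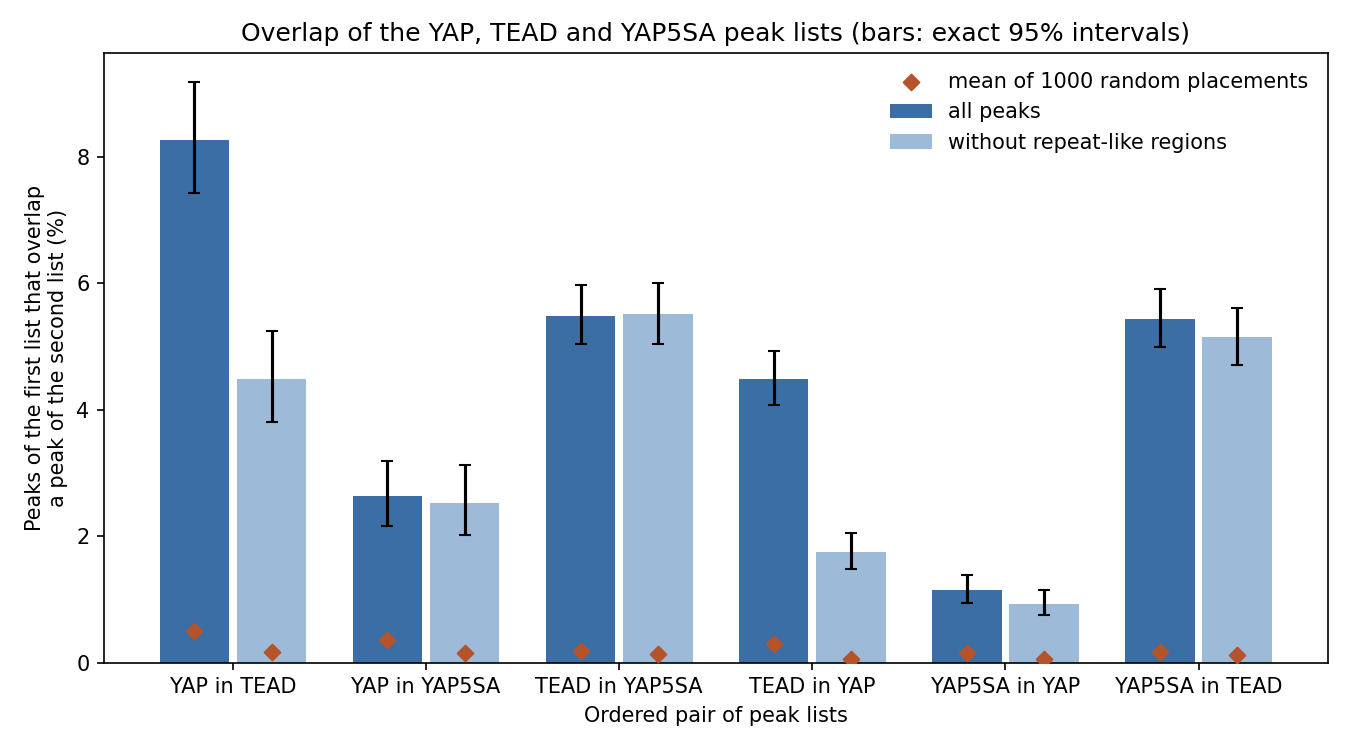
Bars give the percent of peaks of the first list that overlap a peak of the second list, for all peaks (dark) and without repeat-like regions (light), with exact 95% intervals; diamonds mark the mean of 1000 random placements. YAP in TEAD falls from 8.28% to 4.48% without repeat-like regions, while TEAD in YAP5SA stays near 5.5%. For YAP in TEAD the ratio to the placed mean rises from 16.3 to 27.3.

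The next comparison asked whether the sites of endogenous YAP and of tagged YAP5SA coincide within TEAD sites. Among the 512 TEAD peaks that overlapped a YAP5SA peak, 77 also overlapped a YAP peak (15.0%, 95% interval 12.1 to 18.4), against 341 of the other 8809 TEAD peaks (3.87%, 3.48 to 4.30). Of the 320 YAP peaks at a TEAD peak, 70 overlapped a YAP5SA peak (21.9%, 17.5 to 26.8), against 32 of 3547 YAP peaks elsewhere (0.902%, 0.618 to 1.27). YAP5SA peaks showed the same: 73 of 523 at a TEAD peak overlapped a YAP peak (13.96%) and 38 of 9093 elsewhere did (0.418%). Peaks of all 3 lists met in 73 regions, where the peak centres of the lists lay within a median range of 135 bp.

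The odds ratio for TEAD peaks was 4.40 (95% interval 3.37 to 5.73; Fisher's exact test, two-sided, p = 5.54e-22). It was 30.8 (19.9 to 47.6) for YAP peaks and 38.7 (25.8 to 57.9) for YAP5SA peaks split by overlap with TEAD, and without repeat-like regions 66.3 (40.2 to 109) and 41.8 (26.5 to 66.0). For TEAD peaks it was 12.6 (8.93 to 17.7) without repeat-like regions, where 12.53% and 1.13% of TEAD peaks overlapped a YAP peak, and 6.92 with a reciprocal overlap of 50%; in the other settings it ran from 3.60, with lists of 3867 peaks, to 6.08, with peak centres within 250 bp. A reciprocal overlap of 50% left 36 YAP peaks matched in both other lists, and 57 regions with all 3 lists remained without repeat-like regions. TEAD peaks at a YAP5SA peak also scored higher and were wider. Without repeat-like regions their median score was 354 against 73.7, and their median width 392 bp against 203 bp. In the highest-scoring of 10 equal parts of that TEAD list, 11.4% overlapped a YAP peak, whether or not they met YAP5SA. No odds ratio here was adjusted for score or width. Coincidence of YAP and YAP5SA thus cannot be told apart from overlap of both with strong TEAD peaks.

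The 10 TEAD peaks with the highest scores were nearly all shared: 9 lay in regions with peaks of all 3 lists. Among them were peaks on chromosome 5 from 1326297 to 1329202, chromosome 14 from 62221873 to 62222485, chromosome 12 from 13678052 to 13679844, chromosome 3 from 76546309 to 76547339 and chromosome 6 from 132272336 to 132272890, each with the highest listed score of 3100. The peak on chromosome 1 from 59608388 to 59609306, with a score of 2978, met a YAP peak and no YAP5SA peak. The chromosome 5 region was also the highest-scoring YAP5SA peak (score 3100), followed by the chromosome 14 region (2562) and the chromosome 12 region (2152). The YAP peaks in these 3 regions scored 856, 528 and 424. One of the 10 highest-scoring YAP5SA peaks, on chromosome 1 from 220826432 to 220826706 (score 535), overlapped neither a YAP nor a TEAD peak. That peak belongs to 1 of the 19 YAP5SA clusters that held neither a YAP nor a TEAD peak. For those clusters cloned DNA in the tagged library could not be excluded, so the peak cannot be taken as YAP5SA binding away from TEAD.

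The 10 highest-scoring YAP peaks were of another kind. They included peaks of 17.8 kb and 21.2 kb on chromosome X, 40.3 kb on chromosome Y, 18.2 kb on chromosome 8, 21.1 kb on chromosome 2 and 18.7 kb on chromosome 17, and one of 85.9 kb on a contig of chromosome 9. Of these 10 peaks, 9 lay on a contig or within 2 Mb of a stretch of over 2.5 Mb that had no peak in any list; the other lay on chromosome 5 from 9939 to 11856. The top of the YAP list by score was thus made up of such regions.

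The third comparison asked whether shared peaks are the stronger ones of each list. Shared TEAD peaks had a median score of 134 where they met a YAP peak, against 75.1 for the rest, and of 527 against 75.1 without repeat-like regions (150 shared peaks). YAP peaks that met a TEAD peak had a median of 73.2 against 57.7 (65.7 against 57.6 without these regions), and YAP5SA peaks that met a YAP peak a median of 79.6 against 56.9 (78.1 against 56.9). Overlap was most frequent at the top of each list. With each list split by score into 10 equal parts, without repeat-like regions, 31.4% of the 855 TEAD peaks of the highest part overlapped a YAP5SA peak (95% interval 28.3 to 34.6) and 11.4% a YAP peak (9.30 to 13.7). For the next part these shares were 9.83% and 1.29%. Of the 100 highest-scoring TEAD peaks in the full list, 65 met a YAP5SA peak, 50 a YAP peak and 34 both; without repeat-like regions these counts were 63, 42 and 30. Of the 100 highest-scoring YAP5SA peaks 74 met a TEAD peak and 32 a YAP peak (69 and 26 without repeat-like regions). Of the 100 highest-scoring YAP peaks 57 met a TEAD peak and 19 a YAP5SA peak, but without repeat-like regions these counts were 23 and 15, and 75 met neither.

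The probability that a shared peak scored higher was 0.719 for YAP peaks at TEAD (95% interval 0.685 to 0.754), 0.683 for TEAD peaks at YAP (0.653 to 0.710) and 0.766 for YAP5SA peaks at YAP (0.708 to 0.818). Each had p = 1e-05, the smallest value that the two-sided permutation test can give. Among peaks in the middle 50% of widths the call ended for TEAD (0.455, 0.389 to 0.519, 66 shared peaks) and for YAP5SA (0.507, 0.373 to 0.639, 22 shared peaks), with permutation p of 0.209 and 0.916. Of the 932 highest-scoring TEAD peaks, 10% of the list, 96.1% lay in the widest 25% of the list, which that setting leaves out.

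**Figure D2:**
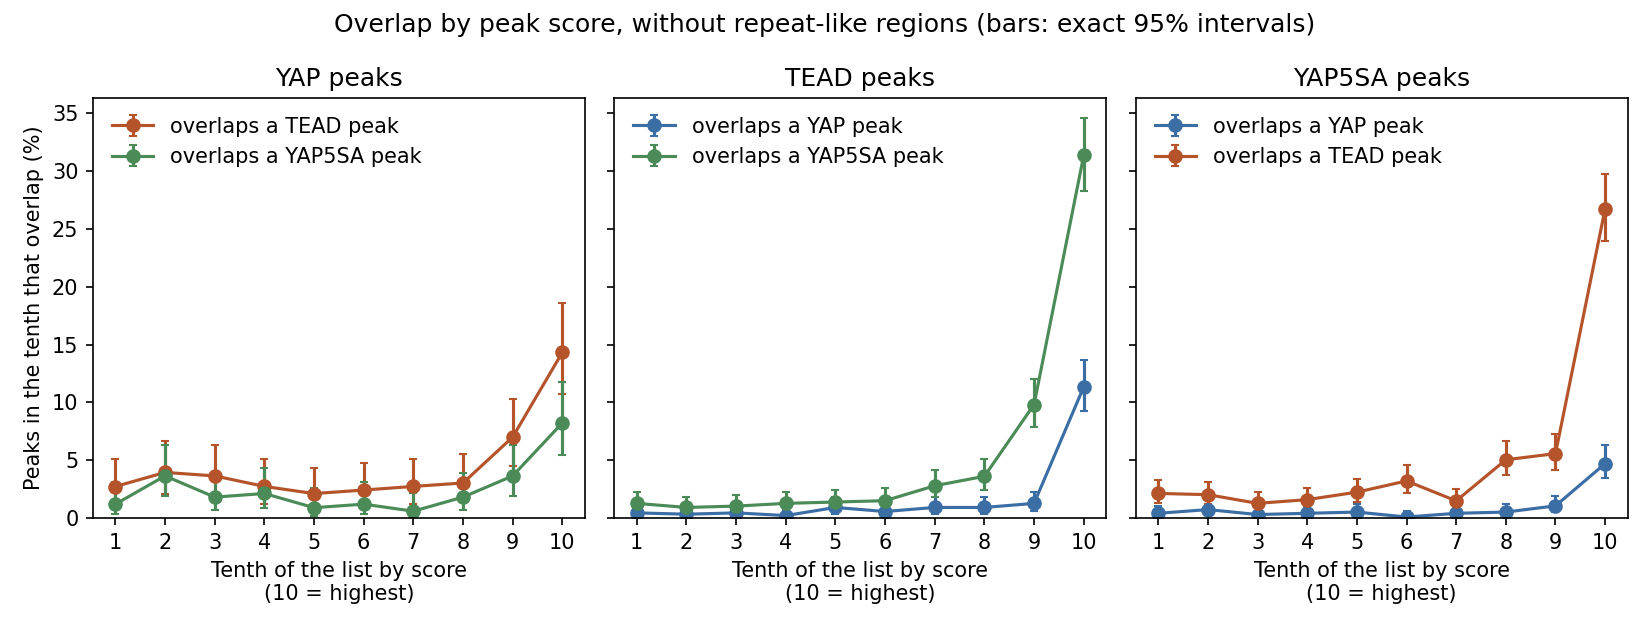
Each panel plots, for 1 list without repeat-like regions, the percent of peaks in each of 10 equal parts of the list by score (x axis, 10 the highest) that overlap a peak of each other list (y axis), with exact 95% intervals. In the TEAD panel the share that overlaps a YAP5SA peak reaches 31.4% in the highest part and is 9.83% in the next.

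The last comparison asked how many peaks lie in clusters, since the series' title concerns super-enhancers, which are dense groups of enhancers. TEAD peaks were strongly clustered: 2749 of 9321 (29.5%, 95% interval 28.6 to 30.4) lay in 559 clusters, 22.8 times the mean of random placements. In the YAP list 341 peaks (8.82%, 7.94 to 9.76) formed 58 clusters, 9.86 times the placed mean. In the YAP5SA list 136 peaks (1.41%, 1.19 to 1.67) formed 36 clusters, 2.61 times the placed mean. Of these 136 peaks, 72 lay in 19 clusters that held neither a YAP nor a TEAD peak. Cloned DNA in the tagged library or a copy number gain could not be excluded for those clusters. The YAP5SA ratio therefore cannot be read as clustering of binding sites alone. Without repeat-like regions 25.7% of TEAD peaks lay in 510 clusters and 106 YAP5SA peaks in 29 clusters (1.14%, 0.933 to 1.38), whereas 12 YAP peaks in 4 clusters were left (0.366%, 0.189 to 0.639). These shares were 47.3 times the placed mean for TEAD, 2.45 times for YAP5SA and 5.93 times for YAP. The lists differ in length. With each limited to its 3867 highest-scoring peaks, the ratios were 29.5 for TEAD, 9.86 for YAP and 8.85 for YAP5SA. Number and score of the peaks change together in that setting, so the change in ratio cannot be put down to list size alone.

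No random placement of the 1000 reached the observed share in any full list (one-sided permutation test, p = 0.001, the smallest it can give), and without repeat-like regions 5 of 1000 did for YAP (permutation p = 0.00599). With a distance of 5 kb the shares were 5.84% for YAP, 19.2% for TEAD and 0.530% for YAP5SA, and with 25 kb the YAP5SA share was 4.16%; against random shifts of up to 500 kb the ratios to the placed mean were 3.47 for YAP, 4.12 for TEAD and 1.83 for YAP5SA.

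The largest YAP clusters were 37 peaks on chromosome 1 from 121351852 to 121463182, 26 on chromosome Y from 13800945 to 13869665, 16 on chromosome 11 from 51567059 to 51594034 and 14 on chromosome 21 from 10819150 to 10858699. Clusters of 12 peaks on chromosomes 7 and Y came next. The chromosome Y and 21 sites also held large TEAD clusters, of 38 peaks (13801041 to 13869894) and 55 peaks (10774158 to 10860690). Other large TEAD clusters were 44 peaks on chromosome 10 from 39076593 to 39153986, 27 on chromosome 4 from 49093193 to 49158713 and 50 on a contig assigned to no chromosome. Without repeat-like regions the largest TEAD clusters were 21 peaks on chromosome 10 from 18841633 to 18860538, 14 on chromosome 3 from 150010645 to 150063119 and 13 on chromosome 12 from 76017408 to 76060944. The chromosome 3 cluster held 3 YAP5SA peaks and no YAP peak, and the chromosome 10 cluster neither.

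The largest YAP5SA clusters were 8 peaks on chromosome 1 from 52924012 to 52947687, 7 on chromosome 8 from 144893123 to 144897556, 7 on chromosome 18 from 13673154 to 13675791, 6 on chromosome 3 from 196831809 to 196867182 and 6 on chromosome 19 from 50605087 to 50640937. Those on chromosomes 1, 8 and 3 held neither a YAP nor a TEAD peak, as did 19 of the 36 YAP5SA clusters. The chromosome 18 cluster held 3 TEAD peaks and 1 YAP peak, and the chromosome 19 cluster 14 and 1. A cluster of 5 YAP5SA peaks on chromosome 21 from 17923630 to 17946175, among the largest without repeat-like regions, lay among 7 TEAD peaks and 1 YAP peak.

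**Figure D3:**
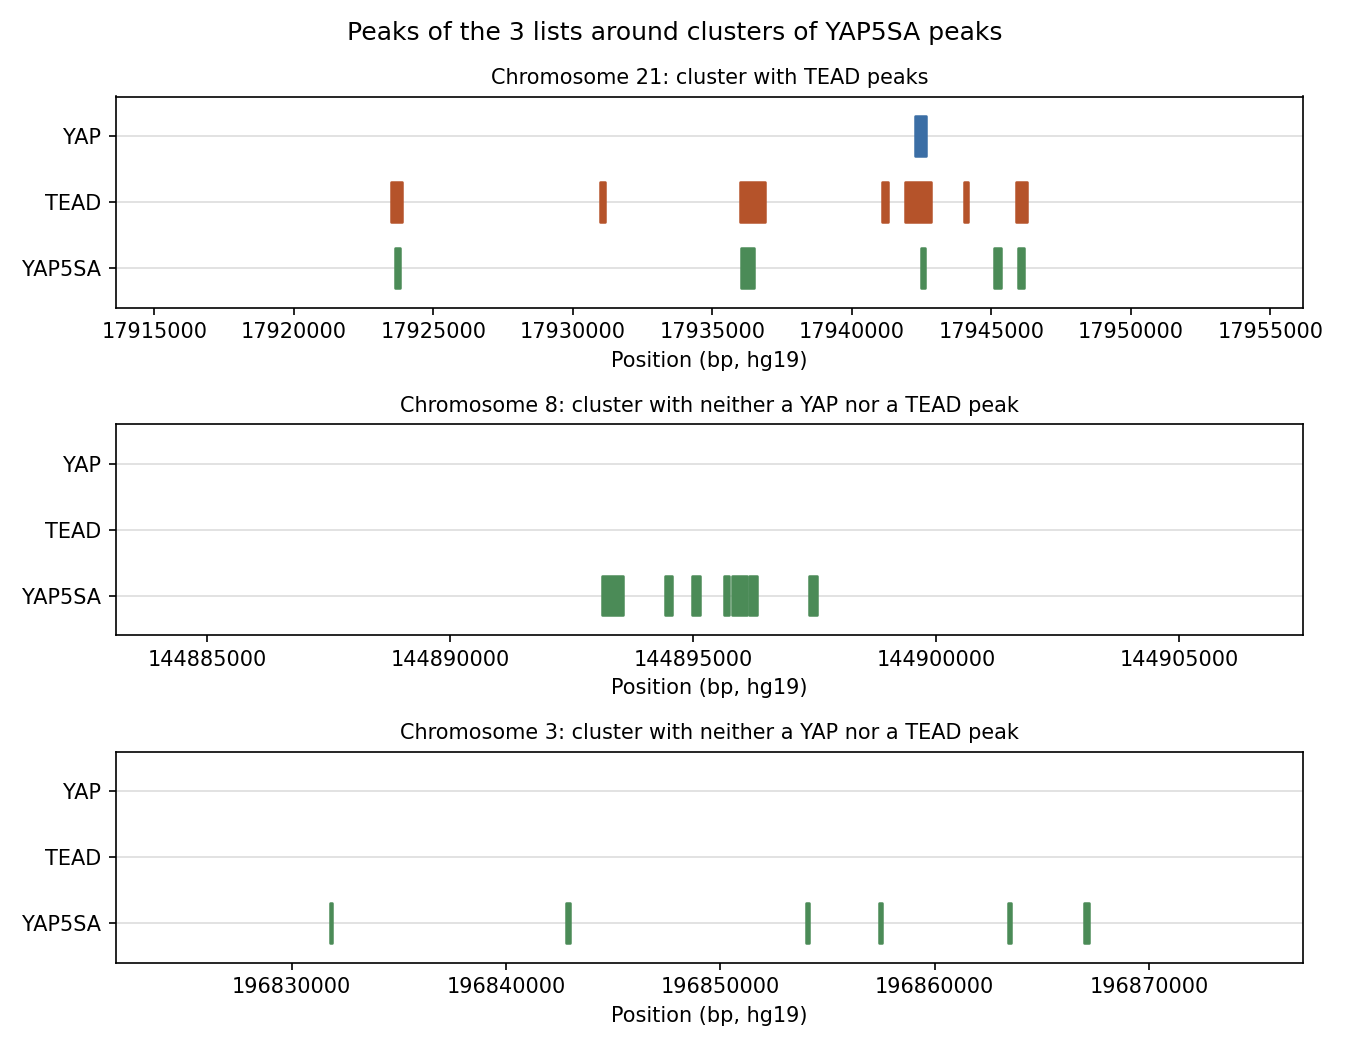
Boxes mark the peaks of each list (rows) along hg19 position in bp (x axis, to scale within each panel) around 3 clusters of YAP5SA peaks. The chromosome 21 cluster has 5 YAP5SA peaks among 7 TEAD peaks, while the clusters on chromosomes 8 (7 peaks) and 3 (6 peaks) have no YAP or TEAD peak beside them.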

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

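Across the alternatives, 84 values were recomputed for 14 results, and 81 kept their direction and their side of the threshold or, for the count of regions in all 3 lists, stayed within 1.5 times. The settings without repeat-like regions and with placement outside peak-free stretches of over 1 Mb were chosen after seeing the data. All 6 overlap shares stayed above every random placement under each setting run, including shifts of up to 500 kb and omission of chromosome 1. A kept direction did not mean a kept size. Without repeat-like regions the share of YAP peaks in clusters fell from 8.82% to 0.366%, and its ratio to the placed mean from 9.86 to 5.93. The exceptions by this count were few. With a reciprocal overlap of 50%, regions in all 3 lists fell from 73 to 36, by the stricter overlap itself and because YAP peaks matched in both other lists were counted there. Among peaks of middling width, the probability that a TEAD peak shared with YAP scored higher turned from 0.683 to 0.455 and that for a YAP5SA peak shared with YAP fell from 0.766 to 0.507; the cause was not tested further. The range was 0.617 to 0.719 for YAP peaks at TEAD, 0.455 to 0.831 for TEAD peaks at YAP and 0.507 to 0.766 for YAP5SA peaks at YAP. Random shifts of up to 500 kb raised the placed share of clustered TEAD peaks from 1.30% to 7.16%, against 29.5% observed. Placement outside assembly gaps and the promoter, motif and gene list alternatives were not run, for want of an hg19 sequence and annotation in the work. With 1 library per group no replicate could be left out. No paired analysis was possible because each group has 1 library. Read depth, which limits how many weak peaks are called, is unknown, so the share of peaks with no partner cannot be read as a share of unshared sites.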

Other observations

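The tests in this part were chosen after the data were examined, except those with windows of 200 bp and with peaks of middling width, although for copy number and cloned DNA the prediction preceded the value.

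TEAD peaks in clusters met YAP more often than lone TEAD peaks. The 2200 clustered peaks compared here lay in 510 clusters. Neighbours in a cluster are not independent, so the p-values of this comparison are too small and its intervals too narrow. Without repeat-like regions, 66 of 2200 clustered TEAD peaks overlapped a YAP peak (3%) against 84 of 6348 lone ones (1.32%), an odds ratio of 2.31 (95% interval 1.67 to 3.20; Fisher's exact test, two-sided, p = 1.07e-06, Benjamini-Hochberg adjusted over 12 tests 1.29e-05). Clustered peaks also scored higher, with a median of 107 against 70.5, and within the highest-scoring 20% of the list the shares were 7.09% and 5.73% (odds ratio 1.26, 0.850 to 1.86; exact p = 0.270). Overlap with YAP5SA was 6.27% for clustered and 5.25% for lone TEAD peaks (odds ratio 1.21, 0.985 to 1.48; exact p = 0.0735). In the highest-scoring 20% it went the other way: 119 of 733 clustered TEAD peaks (16.2%) and 233 of 977 lone TEAD peaks (23.8%) met a YAP5SA peak, an odds ratio of 0.619 (0.484 to 0.791; Fisher's exact test, two-sided, p = 0.000109, adjusted p = 0.000652).

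The lists were also spread differently over the chromosomes. Without repeat-like regions, chromosome 17 held 515 TEAD peaks (6.03% of the list) and 294 YAP5SA peaks (3.16%), and chromosome 19 held 306 (3.58%) and 173 (1.86%). Chromosome X held 100 TEAD peaks (1.17%) and 460 YAP5SA peaks (4.94%), an odds ratio of 0.228 (Fisher's exact test, two-sided, p = 2.85e-51). The YAP list, which was not tested here, held 3.08% of its peaks on chromosome 17, 1.65% on 19 and 3.51% on X. On each of these chromosomes the YAP share lay nearer to that of YAP5SA than to that of TEAD. This did not hold on every chromosome where the TEAD and YAP5SA shares differed. On chromosome 7 the shares were 5.77% for YAP, 6.82% for TEAD and 4.22% for YAP5SA. The YAP share lay nearer to that of TEAD on chromosomes 1 and 13 as well. Of 24 chromosomes tested, 6 held a higher share of the TEAD list and 9 a higher share of the YAP5SA list after Benjamini-Hochberg adjustment. TEAD density ran from 0.647 peaks per Mb on chromosome X to 6.35 on chromosome 17, leaving out chromosome Y, and YAP5SA density from 2.16 on chromosome 10 to 4.36 on chromosome 22. Peaks are not independent, least of all in clusters, so these p-values are too small.

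Shared peaks scored higher in each list. An advantage of wider peaks in meeting others was tested with windows of 200 bp around peak centres, where the lowest of the 3 lower bounds of the probability was 0.634, above 0.5; the tables argue against called width alone, although among peaks of middling width the relation was not seen for TEAD (0.455) or YAP5SA (0.507). Repeat-like regions, as defined here, scoring high in every library were argued against. Without them the lowest lower bound was 0.598 for the same 3 pairs, and 0.5545 over all 6 ordered pairs (YAP peaks at YAP5SA). The filter used no repeat annotation, so repeats outside its definition stayed in and are not argued against. The view that the lower-scoring 50% of each list holds only randomly placed peaks was argued against as well. Without repeat-like regions its overlap was at least 8.77 times the mean of random placements in all 6 ordered pairs. The overlapping shares were small, from 0.491% (TEAD in YAP) to 3.05% (YAP in TEAD). The rest of these peaks may still be randomly placed. The placements ran over whole chromosomes, and no local shift was run for this part of each list. Background peaks that the lists have in common are therefore not argued against. Stronger occupancy at shared sites may underlie the pattern and was not tested, and score and width could not be separated at the top of the TEAD list.

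Peaks over 5 kb in the YAP list were mostly near places that no list covers. Of the 29, 26 (89.7%, 95% interval 72.7 to 97.8) lay on contigs or within 2 Mb of a peak-free stretch of over 2.5 Mb, against 11.6% of the 3707 YAP peaks of at most 1 kb. Repeat sequence beside assembly gaps is a candidate explanation, found and tested on the same data. A signal of the YAP antibody alone was tested by overlap. Of the 29, 25 (86.2%, 68.3 to 96.1) overlapped a TEAD or YAP5SA peak, above the 34.5% reached at most in 1000 random placements of these peaks. Most of these places thus held a peak of another list too. The test cannot decide whether the signal is mainly that of the YAP antibody. An overlap of 1 bp counted, and placements ran over whole chromosomes and were not kept near peak-free stretches. No biological explanation was tested.

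Of the 36 YAP5SA clusters, 19 held neither a YAP nor a TEAD peak, and their 72 members had a median width of 163 bp, the same as the 9480 YAP5SA peaks outside clusters. A local copy number gain may raise peaks of every list, but 40 YAP and TEAD peaks lay within 250 kb of these clusters against a placed mean of 42.8 (SD 15.9). A count at or below that mean had been set in advance as evidence against a gain. The gap is smaller than the spread of the placements, a requirement added after the value was seen. These clusters were also chosen for holding no YAP or TEAD peak in their span, which the counting window includes. The placements carry no such condition, so the observed count is biased downward and the test cannot decide on a gain. Extra copies of cloned DNA in the tagged library could give rows of peaks; members scored higher than YAP5SA peaks outside clusters with a probability of 0.687 (95% interval 0.618 to 0.751), but members of the 17 clusters that did hold a YAP or TEAD peak did so too (0.738, 0.666 to 0.803). The 2 cannot be told apart here without hg19 exons and the BirA library. Binding of YAP5SA away from TEAD stays open as well and was not tested.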
